A study of Mus musculus with 8 samples.

How the data were processed

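The series measured RNA from mHippoE-2 cells that express FLAG-HA-tagged mouse RBM45, as iCLIP libraries made with an antibody against HA and as size-matched input libraries made in parallel. It has 8 libraries, 2 in each of 4 groups (WT CLIP, WT input, Mettl3 knockout CLIP, Mettl3 knockout input), taken from the sample titles. Only the labels of the knockout samples state the crosslinking, as UV light at 150 mJ/cm2 given 2 times to cells grown to 85% confluency.

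Per the submitters' processing notes, the tools were Novoalign 3.09.00, MACS2 2.1.1.20160309, bedtools 2.25.0, HOMER 4.11.1 and deepTools 3.2.1, with the mm10 build; their order and settings are not given in the sources used here. The deposited peak lists of WT CLIP replicates 1 and 2 were called per library, and the peak names in them carry MACS2 and a p threshold of 0.005. Each deposited peak has the authors' score, which equals 10 times the −log10 p rounded down in 100% of lines. It also has a fold (a ratio of pileup over background, by the authors' peak caller) and the −log10 p itself, deposited by the authors with no q-value used here. Whether input served as the control of the peak caller is not given in the sources used here. Many deposited lines were repeats of the same peak (267229 of 654978 in replicate 1, 237090 of 581790 in replicate 2), which were removed. The numbers in the peak names run up to 488294 and 453466, and 78.3% and 74.9% of them are present. Of the distinct peaks 99.3% and 99.2% overlapped a gene on their own strand, and 5181 and 4904 intervals stand on both strands. How strand was assigned to peaks is not given in the sources used here, and it may have been taken from the gene annotation. The shares on the gene's strand would then hold by construction, the strand of a peak would say nothing about the RNA, and an interval under genes of both strands counts 2 times, as in introns of Gm15545 and Bcl2l12 (chromosome 7, 44993355 to 44993553). Among replicate 1 peaks 84.0% had the least width of 30 bp, and in replicate 2 83.4%. In the deposited shared list, 16399 pairs of a replicate 2 and a replicate 1 peak were equal to the pairs recomputed here as overlapping by at least 50% of the replicate 2 peak. The shared list ranks peaks here by the lower of the replicates' scores. The depth per library is unknown, so that shares carry Wilson 95% intervals over peaks, which cover counting error only.

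A deposited count table, made with featureCounts 1.6.3 per its file header, gives the shared peaks as features. Its 8 library columns, and the 8 of its summary, carry names that match no sample's labels, and they were not used in any step. The 5 planned contrasts (knockout against WT in CLIP, in input and in CLIP over input, and CLIP over input in each genotype) were therefore not run. The same holds for the planned gene list tests on them and for the tests of motifs, regions and peak genes against the knockout change. A genome sequence was not used here. Sequence came from GENCODE M21 (GRCm38) transcripts, the lengths of 81033 of which were equal to the sum of their exons with 0 exceptions, so that intronic sequence was read only where a transcript of the comprehensive set covers it.

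Peaks were placed on the GENCODE M21 basic gene set by their midpoint. Overlap between replicates was compared with 100 circular shifts of replicate 2 positions within the span of their gene, with a fixed seed. For overlap split by −log10 p or by region, the shifts stayed within the exons or introns of the gene. Region classes were compared with shifts within the gene span, with 20 shifts for each single replicate list. Distances to stop codons and splice sites were compared with 10000 random placements along the same transcript or introns, as binomial draws per peak. Motifs were counted in exonic peaks and in windows of equal width 500 nt up and downstream in the same transcript, in any region of it. Overlapping sites each counted, so that a stretch of more than 5 U holds more than 1 UUUUU site. Shares were tested with Fisher's exact test and densities per peak with a two-sided sign-flip permutation test of 100000 resamples, both adjusted by Benjamini-Hochberg over 5 motifs. Peaks higher and lower than their windows were compared with a two-sided exact sign test, not adjusted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.

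Shared peaks per gene were tested one-sided with an exact Poisson test against the mean of 100 shifts within the exons or introns of the gene, raised by 0.01, with Benjamini-Hochberg adjustment over 15642 genes with peaks in both replicates. The gene lists were m6A machinery, immediate early and short-lived mRNAs, SR and TRA2 splicing factors, hnRNPs, ALS and FTD genes, neuronal differentiation, neural progenitor, axon guidance, synaptic adhesion and scaffold, nuclear long non-coding RNAs, interferon response, cell cycle, p53 pathway, chromatin regulators, extracellular matrix, markers of astrocytes, oligodendrocytes, microglia and endothelium, mitochondrially encoded genes, abundant structured RNAs, ribosomal proteins, snoRNAs and replication-dependent histones. Each list with at least 5 genes in the test, 22 of 24, was compared with 10000 random lists matched on expected shared peaks in 10 bins (members drawn with replacement within a bin, two-sided), and with all other genes by Fisher's exact test.

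The groups, the overlap, region and DRACH and GAC comparisons, the gene lists and the rule for named genes were fixed before the data were examined. That rule names Mettl3 and Rbm45 first, then the 10 shared peaks with the highest score and the 10 genes with most shared peaks, with ties kept. One gene with a small p in the gene test is not reported here. The rest was decided after results were seen. The Poisson test of genes was not planned; its expectation was first floored at 0.01 (286 genes) and then raised by 0.01 (269 genes). Both list tests were seen before the matched one was made the main one. The motifs GGAC, GACGAC and UUUUU, counts of all 64 trinucleotides and 256 tetranucleotides, and the test of densities were added. The test of densities followed shares of DRACH and GAC that missed the threshold. The set of peaks with a fold of 10 or more, that of peaks wider than 100 bp, the fold classes and the shuffles that keep every dinucleotide followed the higher density seen in strong peaks, so the GAC result was found and tested on the same data.

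The steps were tested on simulated data. With replicate 2 positions shifted once, the overlap was 0.997 times that of further shifts over 344700 peaks, and 0 of 15642 genes were called. Those positions came from the same shifts as the expectation. This checks the computation only, not how the tests behave where real lists share coverage or runs of peaks. With 3 shared peaks planted in each of 100 genes 12 were called, with 6 planted 62 of 100, and 0 other genes. Region shares of 16294 shifted peaks gave 1.05 times the shifted share in 3' UTRs. Of 22 lists 0 passed without planted sharing, and the chromatin regulators passed with an adjusted p of 0.0044 when each of them was given a shared peak. GAC gave an adjusted p of 0.81 in 600 random sequences and 5e-05, the smallest the resamples can give after adjustment, when it was written into 30% of them. Alternatives covered the overlap rule, the strand, peaks above the median score, single replicate lists, the distance of windows, the space of shifts and the background of lists.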

Results

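RNA bound by RBM45, an RNA-binding protein with RNA recognition motifs, was profiled by iCLIP in mHippoE-2 cells, a transformed mouse hippocampal neuronal line. iCLIP crosslinks protein to RNA with UV light, pulls the protein down and sequences the RNA that comes with it. The cells carried a lentiviral mouse Rbm45 with FLAG and HA tags, and an antibody against HA was used for the pull-down. The series holds 8 libraries in 4 groups of 2: CLIP and size-matched input from wild-type (WT) cells, and CLIP and size-matched input from cells without Mettl3, the catalytic subunit of the main mRNA m6A methyltransferase. The stated purpose was to profile RBM45 sites and target genes with and without m6A. The results below come from the peak lists of WT CLIP replicates 1 and 2 and the list of peaks they share. Replicate 1 had 387749 distinct peaks on 17594 genes and replicate 2 had 344700 on 17871 genes, with a median width of 30 bp in each. The number of reads behind these peaks is not given in the sources used here, so the depth is unknown. Nothing in the labels says that the replicates came from separate cultures, and the p-values below therefore measure spread among peaks and genes of these libraries only.

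The Rbm45 transcript itself carried one of the strongest shared peaks. This peak lay in the 3' UTR (mm10, chromosome 2, 76383419 to 76383752, plus strand, 334 nt), with a fold over background of 44.8 in replicate 1 and 50.1 in replicate 2, as the authors' peak caller gave it. Rbm45 held 20 peaks in replicate 1, 10 in replicate 2 and 3 in the shared list, the other two being intronic, at chromosome 2, 76381518 to 76381558 and 76383238 to 76383312. None of its 3 coding-sequence peaks in replicate 1 or 2 in replicate 2 was shared. Mettl3 held 4 peaks in replicate 1, 3 in replicate 2 and 0 in the shared list, none with a fold above 3.51. The 3 shared peaks of Rbm45 were 2.94 times the 1.02 expected from shifted positions, not past the threshold (adjusted p = 0.54, exact Poisson test with Benjamini-Hochberg adjustment).

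Most of the other strongest shared peaks lay in introns. Ranked by the lower of the replicates' scores, the first of 10 was a 49 bp peak on annotated ribosomal RNA, outside any gene (chromosome 17, 39846882 to 39846930), with folds of 7.33 and 4.06. It was followed by an intronic peak of Arid5b, a DNA-binding protein of the ARID family (chromosome 10, 68117047 to 68117429), with folds of 84.5 and 80.7. Vti1a, a SNARE protein of vesicle transport, had a peak with folds of 62.4 and 65.2 (chromosome 19, 55528445 to 55528563). Calu, which encodes the calcium-binding protein calumenin of the secretory pathway, had one with folds of 94.8 and 57.7 (chromosome 6, 29373199 to 29373560). Prune2 held 3 of the 10, between 17044634 and 17046572 on chromosome 19, with folds from 46.9 to 61.9 over both replicates. The Rbm45 3' UTR peak and intronic peaks of Tmcc1 (chromosome 6, 116068830 to 116068930, folds 72.01 and 59.3) and Rbm6, an RNA-binding protein (chromosome 9, 107820848 to 107821358, folds 75.4 and 45.0), completed the 10.

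Strong peaks were shared between the WT replicates more often than weak ones, though not in step with strength. Of replicate 2 peaks with a −log10 p of 20 or more, 81.8% overlapped a replicate 1 peak on the same strand (95% Wilson interval 77.5 to 85.5, 357 peaks). Positions shifted at random within the exons or introns of their genes gave 24.7%. Between 6 and 10 the share was 28.3% (27.2 to 29.4, 6848 peaks) against 6.98% after shifts. Between 2.7 and 3.2, which held 160128 peaks, it was lowest, at 4.57% (4.46 to 4.67) against 3.17%, and in the weakest class, 2.3 to 2.7, it was 8.15% against 5.41%. The ratio to shifts did not rise throughout: it was 1.51 in the weakest class, 5.46 between 10 and 20 and 3.32 at 20 or more. The share itself was 71.4% between 10 and 20 and highest at 20 or more. In that class the higher shifted share (24.7% against 13.1%) limits the ratio. Over all peaks 27070 of 344700 overlapped by at least 1 bp, or 7.85% (7.76 to 7.94). Shifts within the whole gene gave 14678.5 ± 126.5 (SD, 100 shifts), so that the overlap was 1.84 times the shifted one, and 0 of 100 shifts reached it. Shifts within exons or introns gave 15278.3 ± 135.4 (1.77 times). By region, peaks in 3' UTRs overlapped most, at 13.4% against 5.88% after shifts within exons or introns (2.29 times). Introns gave 7.66% against 4.28% (1.79 times) and coding sequence 7.60% against 5.68% (1.34 times). The share fell to 3.95% when 50% of each peak had to be covered, with the ratio to shifts within the whole gene at 2.16. With strand ignored, 26735 of 339796 intervals overlapped (7.87%, 1.842 times shifts within the whole gene). Intervals cover counting error only, and peaks within a gene are not independent. Read coverage along the gene and input did not enter the shifts.

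**Figure D1:**
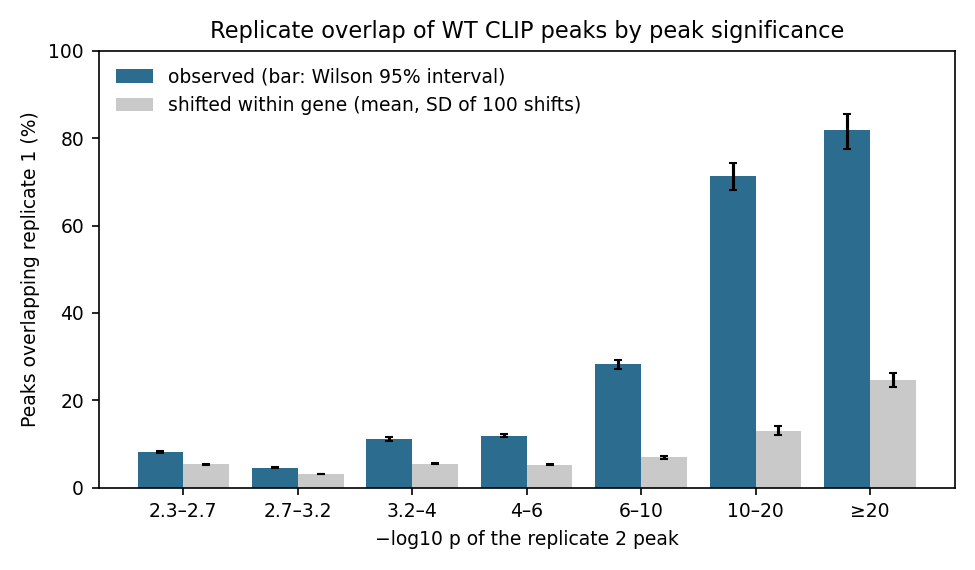
Share of WT CLIP replicate 2 peaks that overlap a replicate 1 peak (%), by the −log10 p of the replicate 2 peak. Blue bars are observed shares with Wilson 95% intervals. Grey bars are the mean of 100 shifts within the exons or introns of genes with their SD. The observed share is 8.15% in the weakest class and 81.8% in the highest.

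Ext1, which encodes a glycosyltransferase that polymerises heparan sulfate, held the most shared peaks of any gene, 48 against 5.31 expected from shifts within its exons or introns (adjusted p = 4.8e-25, exact Poisson test with Benjamini-Hochberg adjustment over 15642 genes with peaks in both replicates). Next by number were Wwox, a WW-domain oxidoreductase, with 36, the GPI-anchored cadherin Cdh13 with 34, Ttc28 with 32, and Atrnl1, the L-type calcium channel subunit Cacna1c and the spindle checkpoint gene Mad1l1 with 31 each. Dock1, an activator of Rac, had 30, and the heparan sulfate proteoglycan Gpc6, the protein kinase C isoform Prkce and Prune2 had 29 each, a tie that makes 11 genes in place of 10. By the same exact test, 8.88 were expected in Cacna1c (adjusted p = 6.3e-06), in Prune2 9.92 (0.0003), in Atrnl1 13 (0.0029), in Gpc6 12.8 (0.0085), in Prkce 13.4 (0.015), in Cdh13 17.7 (0.028) and in Ttc28 16.5 (0.032). Wwox (24.2 expected, adjusted p = 0.24), Mad1l1 (17.9, 0.11) and Dock1 (17.2, 0.11) did not pass this exact test. The test takes the shared peaks of a gene as independent. They were shifted together, however, and can stand in runs, as in Prune2, so these p-values may be too small. Read coverage along the gene and input did not enter the expectation, so an excess of shared peaks need not come from RBM45 binding. All but 3 of these genes had intronic shared peaks only. Atrnl1, Dock1 and Prune2 held 1 exonic shared peak each.

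Counts of shared peaks followed gene length (Spearman's rank correlation 0.379 across genes, which are not independent replicates). The 884 genes with 5 or more shared peaks had a median length of 158.9 kb, against 27.8 kb for all 15642. Shared peaks fell on 6032 of these genes (38.6%), and 269 genes had more of them than shifts gave at an adjusted p of 0.05 (1907 at an unadjusted p of 0.05). Genes of small p in the exact Poisson test, chosen after their values were seen, included Etl4 with 20 against 1.34 (adjusted p = 3.6e-13) and Atxn2, whose product ataxin 2 binds RNA and polyA-binding protein, with 16 against 1.1 (4.7e-10). The guanine nucleotide exchange factor gene Trio held 18 against 2.35 (1.9e-07), the transcription factor gene Bach2 22 against 3.76 (2.3e-07), the microtubule-tip protein Clasp1 14 against 1.32 (2.8e-07) and the splicing regulator Celf2 17 against 2.20 (3.6e-07). Calu held 11 against 0.86 (2.7e-06). This test was not among those planned, and the form of its expectation was changed after a first result had been seen. Here too it takes the shared peaks of a gene as independent, so its p-values may be too small. Coverage and input did not enter it here either, so the 269 genes are not shown to be bound.

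Gene lists fixed in advance were compared by the number of members with a shared peak, and no list of 22 passed an adjusted p of 0.05 against 10000 random lists matched on expected shared peaks. The lists with an unadjusted p under 0.05 were 3. Of 32 chromatin regulators 26 had a shared peak, against a mean of 20.02 in matched lists (permutation p = 0.0074, adjusted p = 0.12), among them Arid1b with 12 shared peaks against 9.66 expected, Kmt2c with 10 against 4.46 and Arid2 with 6 against 0.78, of which only Arid2 passed the gene test. Of 30 synaptic adhesion and scaffold genes 19 had one, against 12.99 (permutation p = 0.011, adjusted p = 0.12), with most in the scaffold gene Magi2, 26 against 13.2 expected, which did not pass the gene test. Of 17 replication-dependent histone genes 9 had one, against 4.24 (permutation p = 0.017, adjusted p = 0.12), for example Hist1h2ag with 2 against 0.42 and Hist1h3b with 1 against 0.07, neither past the threshold. Against all other genes, with no matching, 2 lists passed in Fisher's exact test: chromatin regulators (odds ratio 6.93, adjusted p = 2.5e-05) and axon guidance genes (23 of 35, odds ratio 3.06, adjusted p = 0.016), for which matching gave an adjusted p of 0.32. Of the axon guidance genes, Slit3 held 23 against 10.95 expected and Slit2 10 against 3.47, neither past the threshold. Both list tests were run and seen before the matched one was taken as the main test.

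For the remaining lists the numbers with a shared peak were close to those of matched lists or rested on few genes. They were 9 of 22 genes of the m6A machinery (8.54 in matched lists), including the demethylase gene Fto with 17 shared peaks against 7.38 expected (not past the threshold), 10 of 21 ALS and FTD genes (10.1), 5 of 15 SR and TRA2 splicing factors (2.83) and 7 of 23 hnRNPs (4.94). Neuronal differentiation genes gave 9 of 25 (8.02), neural progenitor genes 7 of 18 (7.80), nuclear long non-coding RNAs 6 of 13 (5.99), immediate early and short-lived mRNAs 8 of 27 (6.49) and interferon response genes 7 of 25 (8.09). Cell cycle genes gave 12 of 30 (10.9), p53 pathway genes 9 of 19 (7.34), extracellular matrix genes 10 of 23 (8.26), ribosomal protein genes 7 of 38 (9.03) and snoRNAs 3 of 5 (1.6). Markers of other brain cell types gave 1 of 7 for astrocytes (1.73), 2 of 7 for oligodendrocytes (1.48), 0 of 6 for microglia (0.58) and 1 of 7 for endothelium (1.66). The mitochondrially encoded genes and the abundant structured RNAs had 0 members with peaks in both replicates and were not tested.

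Single members of these lists passed the gene test over all genes. They were Atxn2 and Taf15, which encodes an RNA-binding protein, among ALS and FTD genes (3 when adjusted over the list alone), and Srrm2, a scaffold of nuclear speckles, with 4 shared peaks against 0.15 among the splicing factors (2 when adjusted over the list alone). Malat1 held 8 against 0.98 and Pvt1 8 against 0.80 among nuclear non-coding RNAs (3 when adjusted over the list alone), whereas Neat1, the paraspeckle RNA, held 19 against 19.03. The adhesion genes Nlgn1 (4 against 0.07), Csmd3 (5 against 0.08) and Cntnap2 (4 against 0.13) passed among synaptic genes (7 when adjusted over the list alone). The netrin receptor gene Dcc passed with 3 against 0.09 (6 of its list when adjusted over the list alone), Arid2 with 6 against 0.78 (1) and the laminin gene Lamc1 with 5 against 0.30 (5). Adjusted over the list alone, 1 member passed among the m6A genes and 1 among the endothelial markers, with 0 over all genes. In the 13 other lists 0 members passed either way.

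Shared peaks were mostly intronic and, over all folds, lay in 3' UTRs more often than shifted positions. Of 16294 shared peaks in genes, 14397 (88.4%, 87.9 to 88.8) had their midpoint in an intron, 969 (5.95%, 5.59 to 6.32) in a 3' UTR, 658 (4.04%, 3.75 to 4.35) in coding sequence, 170 (1.04%, 0.898 to 1.21) in a non-coding exon and 100 (0.614%, 0.505 to 0.746) in a 5' UTR. Positions shifted within the same genes gave 3.51% ± 0.142 in 3' UTRs (SD, 100 shifts), so that the observed share was 1.70 times higher, and 0 of 100 shifts reached it. The ratio was 1.24 in replicate 1 alone and 1.11 in replicate 2 alone (0 of 20 shifts in each), and at folds of 10 or more in both the call was lost (1.34 times, reached by 22 of 100 shifts). Introns lay below shifts, at 0.974 times, in 100 of 100 shifts. Coding sequence (0.991 times), 5' UTRs (0.870 times) and non-coding exons (1.02 times) stayed within the range of the shifts. Replicate 2 peaks that were shared lay in 3' UTRs more often than those that were not, at 5.91% against 3.31% (odds ratio 1.84, adjusted p = 2.9e-59, Fisher's exact test). Protein-coding genes held 96.7% of shared peaks.

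**Figure D2:**
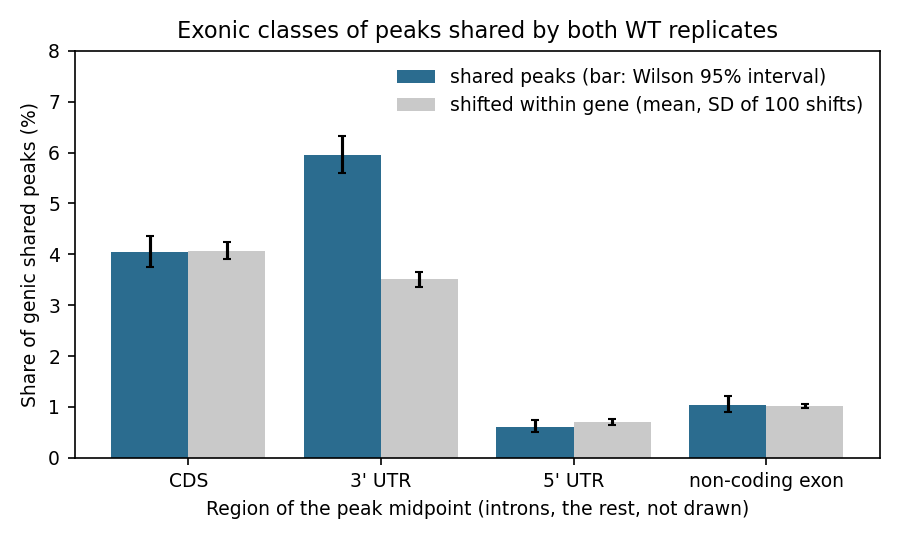
Share of shared peaks in genes (%) whose midpoint lies in each exonic class. Blue bars are observed shares with Wilson 95% intervals and grey bars the mean of 100 shifts within genes with their SD; 3' UTRs hold 5.95% against 3.51% after shifts, and coding sequence 4.04% against 4.07%.

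Peaks near stop codons were also more frequent than random positions in the same transcripts gave. Placement was even along the whole transcript, so this excess is not shown to be separate from that in 3' UTRs. Read coverage along the RNA entered neither expectation. Of 1727 shared peaks in protein-coding exons, 217 (12.6%, 11.1 to 14.2) lay within 150 nt of the stop codon, against 169.2 expected (1.28 times, two-sided p = 0.0002 in a binomial placement test, the smallest that 10000 draws can give). Intronic peaks within 100 nt of a splice site were 2.51% at 5' sites (0.912 times expected, p = 0.07) and 2.53% at 3' sites (0.917 times, p = 0.089) in the same binomial test. In the single replicate lists the coding sequence ratio was above 1, at 1.201 and 1.18, and so was that of 3' splice sites, at 1.04 and 1.03.

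Sequence could be read for 1811 exonic shared peaks, and the share with the consensus of m6A sites, DRACH (D is A, G or U; R is A or G; H is A, C or U), did not differ past the threshold from that of nearby windows. DRACH occurred in 52.7% of peaks and 51.3% of windows of equal width 500 nt away in the same transcript (odds ratio 1.06, 95% interval 0.944 to 1.19, adjusted p = 0.32, Fisher's exact test over 5 motifs). GAC occurred in 39.6% and 42.0% (odds ratio 0.906, 0.804 to 1.02, exact test, adjusted p = 0.13). The number of sites per kb was slightly higher in peaks for DRACH, at 21.1 against 18.6 (difference 2.48 ± 0.70, SE, 1811 peaks; higher in 654 and lower in 637; adjusted p = 0.00095, two-sided sign-flip permutation test), and not past the threshold for GAC, at 15.5 against 14.4 (difference 1.02 ± 0.66, adjusted p = 0.13). For GAC more peaks were lower than higher, 633 against 537, opposite to the mean (p = 0.0055, exact sign test, not adjusted). The test of densities was added after the shares had been seen. Against dinucleotide shuffles of the peaks, DRACH sites were 1749 against 1663.1 (1.05 times, 0 of 100 as high). Peaks with DRACH were fewer than in shuffles, 955 against 983.3, with 3 of 100 shuffles as low. For GAC there were 1346 sites against 1113.5 (1.21 times, 0 of 100 as high) and 717 peaks against 687.6 (1 of 100 as high). Of the motifs added beside these, runs of 5 U occurred in 13.9% of peaks and 5.85% of windows (odds ratio 2.60, exact test, adjusted p = 1e-19). Split by the region of the peak, they occurred in 22.2% against 7.53% for 3' UTR peaks (odds ratio 3.50, exact test, adjusted p = 1.2e-23) and in 2.5% against 2.88% for coding-sequence peaks (odds ratio 0.864, exact test, adjusted p = 0.76). Windows were not held to the region of their peak, so those of 3' UTR peaks can lie in coding sequence. For 3' UTR peaks, G and C made up 37.1% of peaks and 47.3% of windows. The 3' UTR contrast may therefore be one between regions. In the single replicate lists the odds ratio of such runs over all exons was 1.38 and 1.62. In the same shuffles, 238.3 peaks held such a run against 252 observed (1.06 times, reached by 10 of 100 shuffles). UUUUU sites, with overlapping ones counted, were 1.34 times those of shuffles (0 of 100), where their density was 3.12 times that of windows. In the 16 peaks of fold 10 or more in both replicates the density call was lost. It was 9.96 per kb against 3.76, higher in 4 peaks and lower in 4 (permutation test, adjusted p = 0.59). Against shuffles these 16 peaks held 41 UUUUU sites against 18.1 (2.27 times, 0 of 100 as high), 27 of them in the Rbm45 3' UTR peak. Only 4 of the 16 held a run, against 5.97 in shuffles. GGAC occurred in 12.3% and 14.5% (odds ratio 0.828, exact test, adjusted p = 0.055). Its share was lower past the threshold with windows 1000 nt away (odds ratio 0.747, exact test, adjusted p = 0.0045) and in each replicate list alone (0.911, 1.4e-05 and 0.822, 1.4e-17), as was its density in shared peaks (0.800 times, permutation test, adjusted p = 0.0099). The density call was lost above the median score (0.869 times, permutation test, adjusted p = 0.19), and against dinucleotide shuffles the direction turned, with 280 sites against 236.2 (1.19 times, 0 of 100 as high). GACGAC occurred in 19 peaks and 13 windows (odds ratio 2.37, 1.17 to 4.71, exact test, adjusted p = 0.043), a call lost with windows 1000 nt away (odds ratio 1.41), among peaks above the median score (2.49) and in each replicate list alone (1.16 and 1.14). Peaks were also richer in U than windows, at 31.4% against 25.9%.

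GAC and DRACH were denser in the strongest exonic peaks, a split made after the values were seen. In 16 exonic peaks with a fold of 10 or more in both replicates, GAC sites were at 43.7 per kb against 10.9 in their windows (difference 32.8 ± 5.52, SE; higher in 15 and lower in 0; adjusted p = 0.00035, sign-flip permutation test). DRACH sites were at 41.4 per kb against 17.1 (difference 24.2 ± 4.59, SE; higher in 13 and lower in 2; permutation test, adjusted p = 0.0012). These included the Rbm45 3' UTR peak, with 10 GAC and 15 DRACH sites in 334 nt, a coding-sequence peak of Thbs1, which encodes the matrix protein thrombospondin 1, with 16 GAC sites in 243 nt (chromosome 2, 118122442 to 118122684), and a peak of Neat1 with 13 in 336 nt (chromosome 19, 5825233 to 5825568). The Rbm45 peak was also rich in U, with 27 of the 29 UUUUU sites in its transcript and 34.1% G and C. Overlapping sites were counted, so that a longer stretch of U gives more than 1 site. All 16 peaks together held 41 such sites. The GAC ratio of peaks to windows was 0.931 at folds of 1 to 2, 0.944 at 2 to 3, 1.27 at 3 to 5, 2.05 at 5 to 10 and 4.01 at 10 or more, and the DRACH ratio in the same classes was 1.02, 1.08, 1.35, 1.62 and 2.42. At folds of 1 to 2 the GAC difference was not past the threshold (permutation test, adjusted p = 0.41), with 264 peaks higher and 369 lower (p = 3.4e-05, exact sign test, not adjusted). The split was 1 of 5 peak sets and 5 fold classes tried, with 5 motifs in each.

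**Figure D3:**
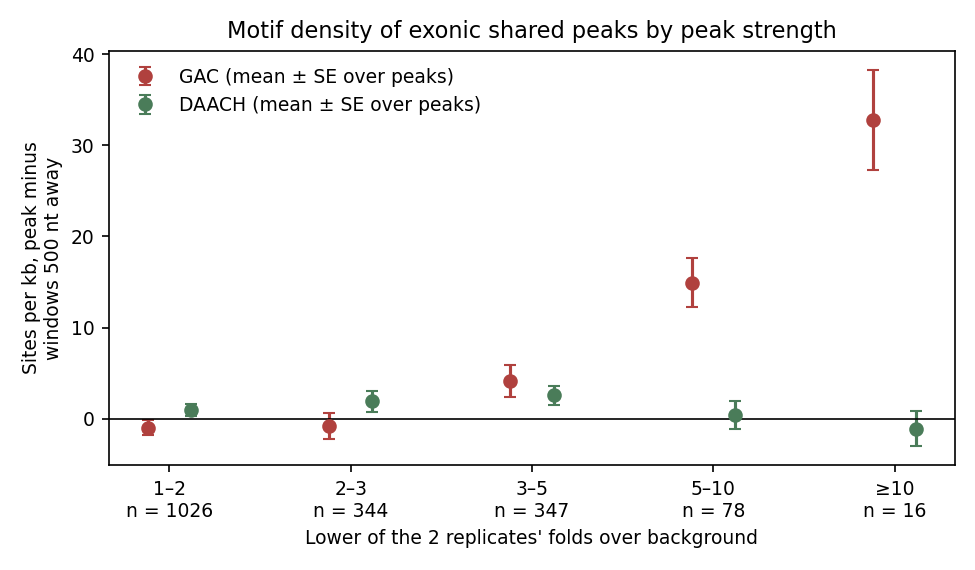
Difference in sites per kb between exonic shared peaks and windows 500 nt away, by the lower of the replicates' folds over background, for GAC and for DRACH sites without GAC (DAACH). Points are means over peaks with SE; the GAC difference is 32.8 ± 5.52 in the 16 peaks of fold 10 or more and −0.98 ± 0.84 in the 1026 peaks of fold 1 to 2.

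The comparison of cells with and without Mettl3, and that of CLIP with input, are not analysed here, since the columns of the count table could not be tied to samples.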

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

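The tests of genes, lists and motif densities, and the settings by peak width and fold, by part of one peak, with replicate 1 first, with shuffles, with other shifts or another floor, with all other genes as background and with single lists for motifs, were chosen only after results had been seen. Of 121 alternatives over 57 results, 78 kept their side of the threshold with no reversal past it, or stayed within the spread. Where neither value passed, a change of direction counts among the 78, as for the GAC odds ratio (0.906, and 1.007 above the median score). For gene lists, a ratio to matched lists was set against an odds ratio. The excess of replicate overlap over shifts held under all 8 of its alternatives (1.58 to 3.65 times), as did the stop codon (1.12 to 1.45) under its own; the cause of the changes below was not tested. The excess in 3' UTRs held in 3 (1.11 to 1.99) but not at folds of 10 or more, where it was 1.34 times shifts and reached by 22 of 100. There coding sequence fell to 0.202, past the threshold, and introns turned to 1.03, reached by 13 of 100 shifts. The share of overlapping peaks was 4.76% at 50% of the replicate 2 peak, 3.95% at 50% of each, 9.26% above the median score, 6.95% with replicate 1 first, 16.8% for peaks wider than 30 bp and 6.06% for those of 30 bp. Above the median score, coding sequence fell to 0.835 times shifts and 3' splice sites to 0.824, both then past the threshold, and genes with a shared peak to 3872, since fewer peaks enter. Without 1 replicate, which puts a single list in place of the shared one, coding sequence turned to 1.18 to 1.201 times shifts, 5' splice sites gave 0.939 to 1.03 and 3' splice sites 1.03 to 1.04. Calls were also gained in single lists, which hold many more peaks: 5' UTRs gave 0.787 to 0.814 and non-coding exons 1.062 to 1.064, outside all 20 shifts of each list. The DRACH odds ratio of 1.05 to 1.06 passed in both (exact test, adjusted p 5.9e-06 and 0.00052), and the GAC odds ratio of 0.948 to 1.00 passed as lower in replicate 2 (exact test, adjusted p 0.00052). The GAC density ratio passed above the median score (1.198), at folds of 10 or more (4.01) and against shuffles (1.21). GGAC density turned from 0.800 to 2.68 at folds of 10 or more and 1.19 against shuffles, and its call was lost above the median score (0.869). The density call of runs of 5 U was lost at folds of 10 or more (2.65). The number of genes called was 328 with shifts within the whole gene and 286 with the floor, and that of lists 2 against all other genes, in place of 0 with matched lists. No paired analysis was possible because the count columns carry no sample names. The settings fixed for the 5 contrasts, for list tests on them and for knockout changes were not run, and with depth unknown, unshared weak peaks cannot be read as unbound.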

Other observations

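The tests of weak peaks, of chance positions, of small RNA copies and of base composition, and the intronic set at folds of 5 or more, were chosen only after the result was seen. Those of unlisted exons, other-strand exons, DAACH and GAC outside the exonic set were written before.

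Several strong shared peaks stood in runs within an intron, chosen here after their values were seen. Vti1a held 4 of the 60 strongest, from 55528445 to 55529233 on chromosome 19, with folds from 34.1 to 65.2 over both replicates. Prune2 held 5 between 17044634 and 17047063 on the same chromosome. Cdk17, a cyclin-dependent kinase gene, had 2 on chromosome 10 (93222219 ends the first and 93222838 starts the second), and Ide, which encodes insulin-degrading enzyme, had 2 on chromosome 19 near 37298641 and 37301670.

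Among exons, the peaks with a fold of 10 or more in both replicates numbered 18. Of these 11 were in 3' UTRs, including a pair in P2rx7, an ATP-gated channel gene (chromosome 5, 122683165 to 122683281 and 122683388 to 122683445, lowest fold 13.7), and one in Nup98, a nuclear pore gene (chromosome 7, 102119895 to 102120080, folds 15.1 and 14.1). Itsn1, an endocytic scaffold gene, had one with folds of 19.4 and 13.8 (chromosome 16, 91828940 to 91829122). Neat1 held 2, and a 5' UTR peak of Cdk11b reached 24.0 and 16.2 (chromosome 4, 155625183 to 155625539). The share of 3' UTRs among shared peaks in genes was 4.14% at folds of 1 to 2, 11.8% at 3 to 5 and 4.85% at 10 or more, where shifts gave 3.61% (1.34 times, reached by 22 of 100 shifts).

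Most replicate 2 peaks had no partner in replicate 1. Chance placement within genes as the whole account is argued against by an overlap 1.844 times that of shifts, reached by 0 of 100. Weak peaks called from little signal stay open as an account: the share with a partner was 11.54 times higher at a −log10 p of 10 or more than below 4, but positions shifted within exons or introns alone gave 3.95 times. The bar of 3 was thus met by placement alone, and that test decides nothing. Against these shifts the share was 4.5 times at 10 or more and 1.54 times below 4, a comparison for which no bar was set. The depth of the libraries stays open, and no biological explanation was tested, since both lists come from one group.

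Of 227 strong shared peaks in genes, with a fold of 10 or more in both replicates, 209 were intronic, as in Arid5b, Vti1a and Calu. Copies of small RNAs or pseudogenes overlapped 1.914% of the 209 intronic peaks (95% interval 0.747 to 4.82), exons of the comprehensive gene set on the same strand 6.699% (4.03 to 10.9) and exons on the other strand 2.392% (1.03 to 5.48), so that none of these could account for most of them. Repeats were not tested, since the genome sequence was not used here. No biological explanation was tested.

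GAC was denser in the 16 strong exonic peaks, where it also ranked 1 of 64 trinucleotides by difference from windows. Base composition is argued against as the whole cause by 1.558 times the GAC sites of shuffles that keep every dinucleotide (0 of 100 as high). DRACH sites with or without GAC alike are argued against by a DAACH ratio of 0.865 in these peaks (difference −1.12 ± 1.94 per kb, SE). DRACH sites that hold GAC were 3.885 times as dense as in windows, so this ratio cannot tell GAC from such DRACH sites. At folds of 3 to 5 DAACH was itself denser, at 1.331 times (347 peaks, permutation test, adjusted p = 0.017). A hypothesis found and tested on these data is that strong RBM45 sites may carry GAC also beyond the exons of the basic gene set. Sequence was read only where an intronic peak lay wholly in an exon of the comprehensive set. GAC outside annotated exons was thus not tested. In 6 such strong peaks the GAC ratio to shuffles was 1.536 (0 of 100 as high), which met the bar set for the ratio. That of DRACH was 1.1 (26 of 100 as high). The least number of 10 peaks, which leaves the hypothesis open, was not in the written prediction. It was lifted and then restored after the GAC value had been seen. The set at folds of 5 or more, added for that reason and holding these 6, had 37 peaks of 26 genes. It gave 1.62 for GAC and 1.22 for DRACH (0 of 100 for each). Whether m6A on these sites matters is untested, since the knockout libraries were not compared.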
